A study of Mus musculus with 9 samples.

How the data were processed

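Gastrocnemius RNA of mice fed a high-fat diet was measured in 9 libraries, 3 per group. Per the labels' protocols, RNA was prepared with a kit for fibrous tissue, had RIN values above 8, and 100 ng entered a stranded kit after selection of polyadenylated RNA, with 51-base single reads. The submitters' processing notes list CASAVA 1.8, cutadapt, RSEM 1.3.1, limma and the genome GRCm38, without the order of the steps or the annotation release.

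The deposited table holds 1 signal value per gene and library and is named by the authors as normalised counts; no header or label records how the authors scaled or filtered it. Read from the values themselves, each deposited signal value is an odd multiple of the smallest value of its library. That is the pattern of a whole number plus 0.5 divided by a scaled library total. All values followed it within 0.001 reads, and the implied scale factors (0.909 ± 0.0328 in the controls, 1.05 ± 0.0584 in the p38α KO and 1.05 ± 0.0243 in the p38α/γ KO; SD, n = 3) had a geometric mean of 1. The recovered whole numbers gave the depths stated in the report but were not tested as counts, because no file states that they are reads. The design allowed for this, so the normalised values were tested on the log2 scale. A group with no inferred read was compared through a floor of 3 reads per library, or values from 0.105 to 0.13, and the lowest ratio was given as "at least". The floor covers counting error only.

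Gene symbols, biotypes and coordinates came from GENCODE M21, which held 13172 of the identifiers; 111 genes had no symbol. No sample column was left unused. The sample groups, the comparisons, the tests, the gene lists and the rule for naming genes were fixed before the data were examined. Genes with a value of at least 1 in at least 3 libraries were tested as log2(value + 1) with limma 3.58.1 in R 4.3.3. The fit held all 9 libraries, used the empirical Bayes step with a trend, and took genes at a Benjamini-Hochberg adjusted p below 0.05 within each comparison. The p-values printed beside genes are limma adjusted p unless an exact permutation test is named. Fold changes are those of value + 1. The comparisons were each knockout against control and the p38α KO against the p38α/γ KO.

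Genes were named by rule. They were Mapk14, Mapk12, Mapk11, Mapk13 and Il15; the 6 genes with the largest rise and the 6 with the largest fall among called genes whose groups did not overlap, leaving out predicted genes, pseudogenes and genes without a symbol; and up to 3 genes with the lowest p from each list that passed or had at least 2 called members. The lists were 37 sets of textbook markers and pathway members, of which 34 had at least 5 tested genes. They were tested with camera in limma, with a preset correlation between genes of 0.01, and adjusted over the lists of each comparison. Each list was tested again with an estimated correlation and with the rotation test fry. Counts "over the list alone" adjust p over that list's genes only. The lists and the genes chosen within them share libraries with the gene tests and are not separate evidence. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

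The script was tested on simulated data of 3 groups of 3 libraries with the depths and control means of these and the same relative spread for all genes. It recovered 17.2%, 34.9% and 41.3% of genes changed 1.5-fold in the 3 comparisons, in the order given, and 92.2%, 89.1% and 98.4% of those changed 2-fold. False calls were 2.86%, 3.33% and 3.75% of all calls. Every simulated library had the same spread, and far fewer genes changed than were called against control. These rates may therefore not hold for the real libraries, where p38α KO 1 stood apart. Likeness of the knockouts was set against 100 simulations of unchanged groups that shared the same controls.

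The samples of each group carry the numbers 1 to 3. To check whether the numbers pair the libraries, the deviations of same-numbered libraries from their group means were correlated across genes. For the p38α/γ KO and the controls the correlations were 0.11, 0.12 and 0.15, each the highest with its own number. That match comes from the data and not from the labels, and whether it exceeds chance was not tested. For the other comparisons at least 1 correlation was negative. The values with the number as a block are given beside the p38α/γ KO results they change.

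The alternatives changed the low-value filter, the pseudocount, the scaling (TMM factors, median of ratios, quantile normalisation), the spread estimate, the libraries in the fit, the block, the thresholds and the list test, and left out each library in turn. Fits on log2 values without a pseudocount, with mean-variance weights, with array weights updated gene by gene and with the block in 6 libraries were chosen after seeing the data. Other splits of the same 6 libraries were tested for each count. No reads were available, so exon use within the targeted genes was not examined.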

Results

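The series measured polyadenylated RNA in the gastrocnemius, a calf muscle made mainly of fast fibres, of mice kept on a high-fat diet for 6 weeks. There were 3 groups of 3 libraries. The first was the control, the second lacked p38α in muscle (p38α KO) and the third lacked both p38α and p38γ (p38α/γ KO). Both proteins are stress-activated kinases, encoded by Mapk14 and Mapk12. The series title places the study in the setting of p38 signalling in muscle, locomotor activity and the secreted factor IL-15. The deposited table held normalised values, and 13137 of its genes were tested. Every value was an odd multiple of its library's smallest value, which gave an inferred depth of 27.9, 26.8 and 25.7 M reads for the controls, 24.5, 24.2 and 27.9 M for the p38α KO and 26.9, 26.7 and 23.8 M for the p38α/γ KO. The labels number the samples of each group but do not say whether they came from separate animals, so p-values measure the spread between these libraries. Library 1 of the p38α KO stood apart. Its correlation with library 3 of its group was 0.961 across genes, whereas the other pairs within groups lay between 0.976 and 0.993. Library 3 lay at the other end of that group. On the main axis of variation between libraries (first principal component, 54.2% of variance), p38α KO 1, 2 and 3 lay at −36, −1 and 9.15. The controls lay between 29.6 and 34 on that axis. The 10 most abundant genes took 26.4% ± 0.557 of the control values, 23.5% ± 1.97 in the p38α KO and 22.2% ± 0.755 in the p38α/γ KO (SD, n = 3).

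Mapk14 RNA fell in both knockouts and Mapk12 RNA fell most in the double knockout. Mapk14 (ENSMUSG00000053436; chromosome 17, 28691329 to 28748406, GRCm38) measured 149.5 ± 7.01 in the controls and 43.2 ± 2.63 in the p38α KO (SD, n = 3). That was 3.41-fold lower (log2 −1.77, SE 0.129, limma adjusted p = 0.000206). In the p38α/γ KO it measured 44.8 ± 9.03, which was 3.32-fold lower (log2 −1.73, adjusted p = 0.000137). Mapk12 (ENSMUSG00000022610; chromosome 15, 89130584 to 89140703) measured 143.3 ± 7.74 in the controls. It was 1.41-fold lower in the p38α KO, at 101.5 ± 4.46 (log2 −0.49, adjusted p = 0.00601), and 4.23-fold lower in the p38α/γ KO, at 33.2 ± 2.18 (log2 −2.08, adjusted p = 9.84e-07). Mapk11 (chromosome 15, 89142486 to 89149628), which encodes p38β, was near 2 in all groups and did not pass the test (log2 −0.07 and 0.15, adjusted p = 0.832 and 0.572). Mapk13, which encodes p38δ, was not among the tested genes. Map2k6 (chromosome 11, 110399122 to 110525522), a kinase that phosphorylates p38 proteins, rose from 19.35 ± 0.712 to 84.0 ± 20.2 in the p38α KO and 68.6 ± 3.86 in the p38α/γ KO, or 4.10-fold and 3.42-fold (adjusted p = 0.000206 and 0.000333).

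Il15 (ENSMUSG00000031712; chromosome 8, 82331632 to 82403222) rose in the p38α KO, from 5.93 ± 1.54 to 10.15 ± 2.09 (SD, n = 3). The difference was 1.61-fold (log2 0.69, SE 0.193, limma adjusted p = 0.0368). In the p38α/γ KO it measured 6.93 ± 1.15, which did not pass the test (log2 0.21, adjusted p = 0.44), and neither did the direct difference between the knockouts (log2 0.48, adjusted p = 0.357). The p38α KO call was lost without control 2 (adjusted p = 0.117), control 3 (0.128), p38α KO 1 (0.0718), p38α KO 2 (0.104), p38α/γ KO 1 (0.0517) or p38α/γ KO 2 (0.0517). It was also lost with the 6 libraries alone (0.0728), and over all alternatives adjusted p ran from 8.55e-05 to 0.128. Two-sided exact permutation tests of the 6 libraries gave p = 0.1, the smallest that 3 against 3 allows, for Mapk14 and Mapk12 in both knockouts and for Il15 in the p38α KO, and p = 0.4 for Il15 in the p38α/γ KO.

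**Figure D1:**
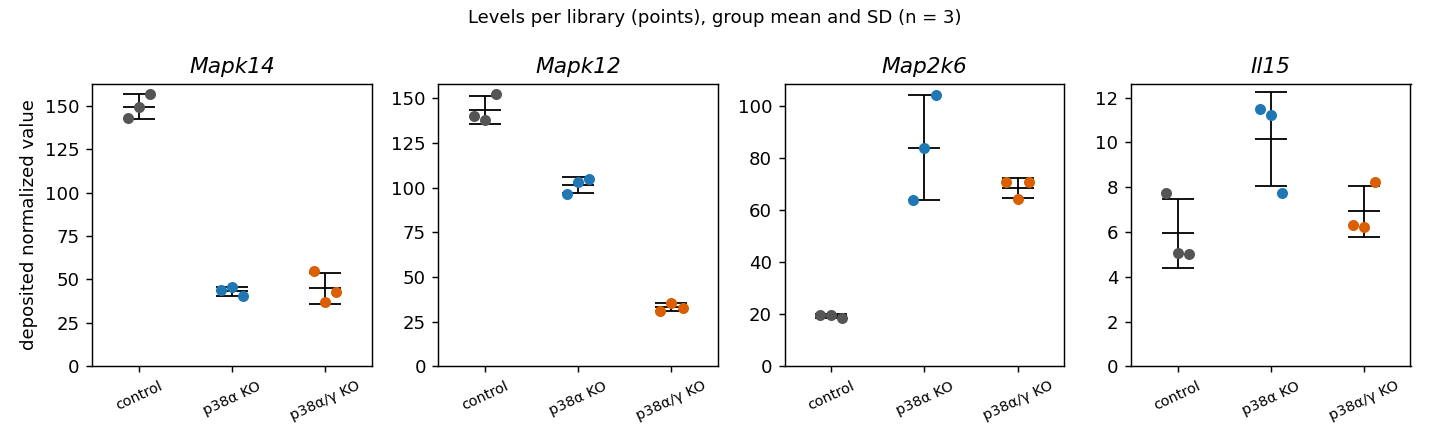
Deposited normalised values of Mapk14, Mapk12, Map2k6 and Il15 in each library (points), with the group mean and SD (bars, n = 3) on a linear axis from 0. Mapk14 was near 45 in both knockouts, Mapk12 stepped down from 143.3 to 101.5 and 33.2, and the single Il15 values of the p38α KO and the p38α/γ KO overlapped.

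The first contrast asked what changed in muscle that lacked p38α. Of the fixed lists, 10 of 19 circadian clock genes, 6 of 21 fast fibre genes and 6 of 29 glycolysis and glycogen genes fell, and 8 of 28 calcium handling genes fell while 3 rose. On the other side, 12 of 20 macrophage genes, 8 of 25 interferon response genes and 6 of 22 myogenesis genes rose. These 7 lists passed as sets with a preset correlation but not with an estimated one (camera adjusted p = 0.671 with an estimated correlation for myogenesis and 0.62 for the others). In the rotation test fry the macrophage (adjusted p = 0.0533) and myogenesis (0.104) lists did not pass, and the others named here did. In all, 2332 of 13137 genes changed (17.8%), 962 higher and 1370 lower, with 171 and 119 of them at least 2-fold. The values of the groups did not overlap for 38.6% of tested genes, where chance gives 10%. The largest rises included Mettl21e, a lysine methyltransferase of muscle, from 2.07 ± 0.0135 to 27.5 ± 16.8 (8.18-fold, limma adjusted p = 0.00128), and Sln, which encodes the calcium pump inhibitor sarcolipin (7.70-fold, adjusted p = 0.0135). The embryonic myosin Myh3 rose 7.39-fold (adjusted p = 0.0225) and the perinatal myosin Myh8 7.48-fold (adjusted p = 0.04). Library 1 of the p38α KO held 106.37 of Myh3, against 28.73 and 10.55 in libraries 2 and 3. The largest falls were in BC023105 (8.00-fold), Igfn1 (7.94-fold), the protease gene Htra4 (7.36-fold), Pla2g7 (7.19-fold, adjusted p = 2.42e-05), Mss51 (6.78-fold) and Lep, which encodes leptin (6.50-fold, adjusted p = 0.0358). Pla2g7, an enzyme that degrades platelet-activating factor, went from 97.8 ± 3.86 to 12.9 ± 2.67 (SD, n = 3). Hmga1b had no inferred read in the controls and 22.2 ± 2.58 in the p38α KO, at least 148-fold higher against a floor of 3 reads per library, which covers counting error only. Its sequence is close to that of Hmga1, and Dynlt1b (11.3-fold higher, adjusted p = 0.00353) has near-identical copies on chromosome 17, so reads can be assigned to either copy.

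Leaving out 1 library ended the calls of Sln (control 3, adjusted p = 0.0511), of Myh3 (control 1, 2 or 3 or p38α KO 2, up to 0.0765), of Myh8 (every control, p38α KO 1 or 2 or p38α/γ KO 3, up to 0.118) and of Lep (control 2 or 3, p38α KO 1 or 2 or p38α/γ KO 3, up to 0.127). The count itself was 852 without control 1, 1034 without control 2, 837 without control 3 and 1456 without p38α KO 2, 2343 without p38α KO 1 and 1364 with the 6 libraries alone. Without p38α KO 1 the log2 change was 2.10 for Sln, 2.04 for Myh3 and 2.06 for Myh8 (2.95, 2.88 and 2.90 with all libraries), without p38α KO 3 it was 3.65 for Myh3 and 3.62 for Myh8, and without control 1 it was −3.66 for Lep (−2.70 with all libraries). Over all alternatives, adjusted p ran from 6.44e-06 to 0.0629 for Sln, from 1.3e-05 to 0.0805 for Myh3, from 0.000127 to 0.118 for Myh8 and from 0.000208 to 0.127 for Lep. The Myh8 call was also lost with a pseudocount of 5 (0.0839), quantile normalisation (0.05) and mean-variance weights (0.0809), and the Lep call with the 6 libraries alone (0.0633) and mean-variance weights (0.0561). Some folds moved by more than 1.5 times with the pseudocount. With 5 in place of 1, and with none, log2 was 1.90 and 3.59 for Sln, 2.07 and 3.53 for Mettl21e, 2.18 and 3.19 for Myh3, 1.92 and 3.49 for Myh8, −2.24 and −3.33 for BC023105, −2.34 and −3.27 for Igfn1, −1.81 and −3.57 for Htra4, −1.95 and −3.00 for Ostn, −1.74 and −3.34 for Lep, 2.69 and 3.86 for Dynlt1b, 0.45 and 2.05 for Lcn2 and 0.98 and 1.91 for Runx1.

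Of 21 genes of the fast fibre list, 6 fell and 15 did not pass the test, and 9 fell when adjusted over the list alone. The list's median was −0.40 on the log2 scale (camera adjusted p = 2.51e-05, and adjusted p = 0.62 with an estimated correlation). Mylk4, a myosin light chain kinase, fell 4.01-fold from 1498 ± 243 to 375 ± 76.8 (SD, n = 3; limma adjusted p = 0.000374), and the fast light chain Myl1 fell 1.70-fold (adjusted p = 0.00676). Of 29 glycolysis and glycogen genes 6 fell, 7 when adjusted over the list alone (camera adjusted p = 0.00147, and adjusted p = 0.62 with an estimated correlation). They included Phka1, a subunit of phosphorylase kinase (2.80-fold, adjusted p = 0.000706), and the glycogen primer Gyg (1.58-fold, adjusted p = 0.00735). Of 28 calcium handling genes 8 fell and 3 rose, and 12 and 4 when adjusted over the list alone (camera adjusted p = 0.00986, and adjusted p = 0.62 with an estimated correlation). The junctophilins Jph2 and Jph1, which hold the surface membrane to the calcium store, fell 1.95-fold and 1.91-fold. Of 19 circadian clock genes 10 fell and none rose, against 13 and 1 when adjusted over the list alone (median −0.79, camera adjusted p = 5.04e-05, and adjusted p = 0.62 with an estimated correlation). Dbp, a clock output gene, fell 3.12-fold (adjusted p = 0.00251) and Nr1d2 1.88-fold (adjusted p = 0.00128). With quantile normalisation the fast fibre (adjusted p = 0.056), glycolysis (0.118) and calcium (0.279) calls were lost.

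Of 20 macrophage and monocyte genes, 12 rose and none fell, 18 when adjusted over the list alone, with a median of 0.98 (camera adjusted p = 1.55e-07, and adjusted p = 0.62 with an estimated correlation). Cd74, the invariant chain of antigen presentation, rose 2.42-fold from 52.9 ± 7.19 to 134.3 ± 49.9 (SD, n = 3; limma adjusted p = 0.00815), and the complement gene C1qb 3.16-fold (adjusted p = 0.0105). Without p38α KO 1 the list's median was 0.80. Of 25 interferon response genes 8 rose, 11 when adjusted over the list alone, and of 17 NF-kB and cytokine genes 5 rose and 1 fell, 10 and 1 when adjusted over the list alone (camera adjusted p = 6.54e-06 and 0.000826, and adjusted p = 0.62 for both with an estimated correlation). Ifit3 rose 2.90-fold (adjusted p = 0.00135) and Lcn2 2.25-fold (adjusted p = 0.00935). Of 22 myogenesis genes 6 rose, 7 when adjusted over the list alone, and of 23 denervation and neuromuscular junction genes 8 rose, also 8 over the list alone (camera adjusted p = 0.0011 and 0.0151, and adjusted p = 0.671 and 0.696 with an estimated correlation). Gadd45a rose 4.81-fold (adjusted p = 0.00198) and the transcription factor Runx1 went from 2.52 ± 0.133 to 10.5 ± 6.22 (adjusted p = 0.00932). Of 25 immediate early genes 8 rose and Nr4a1 fell, 9 and 1 when adjusted over the list alone (camera adjusted p = 0.0136, and adjusted p = 0.62 with an estimated correlation). Ier2 rose from 4.93 ± 0.393 to 9.83 ± 2.21 (adjusted p = 0.00758), and Nr4a1 fell 2.91-fold (adjusted p = 0.00762). Of 29 extracellular matrix genes 4 rose, also 4 over the list alone, and of 16 fibro-adipogenic progenitor genes 1 rose, also over the list alone (camera adjusted p = 0.00632 and 0.0257, and adjusted p = 0.802 and 0.77 with an estimated correlation). Postn, a matrix protein, held 156.75 in library 1, 52.92 in library 2 and 19.61 in library 3 of the p38α KO. Ly6a, the progenitor gene that rose, was not called without control 1 or 3 (adjusted p up to 0.074). Without library 1 the matrix (median 0.06, adjusted p = 0.604), progenitor (0.224), denervation (0.0566) and immediate early (0.0573) calls were lost, and without control 3 the progenitor call was lost (0.085).

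Of 40 oxidative phosphorylation genes 1 rose, Sdhd, a call lost without any 1 of 8 libraries (adjusted p up to 0.136), with the 6 libraries alone or without the trend (0.0587), and none when adjusted over the list alone, and of 40 ribosomal protein genes 3 rose, none when adjusted over the list alone. Their medians were 0.23 and 0.22 (camera adjusted p = 0.000143 and 4.05e-05, and adjusted p = 0.77 and 0.759 with an estimated correlation). The 3 ribosomal calls, Rpl3, Rpl32 and Rps28, were lost in 2, 7 and 5 of the fits with 1 library left out (limma adjusted p up to 0.0981, 0.129 and 0.111). Over the 14 lists that passed, the alternatives gave adjusted p from 7.37e-12 to 0.802. The other 20 tested lists did not pass. The p38 pathway list had 2 of 26 genes higher and 8 lower (6 and 10 when adjusted over the list alone), with Tab2 2.04-fold lower (limma adjusted p = 0.00353), and the list of JNK, ERK and other kinases had 1 of 12 higher and 3 lower (1 and 4 over the list alone). Of 24 myokine genes 4 rose and 1 fell (5 and 1 over the list alone). The 1 that fell was Ostn, which encodes osteocrin, from 28.6 ± 7.67 to 3.51 ± 0.611 (6.43-fold, adjusted p = 0.00037). Antioxidant genes had 6 of 23 higher and 2 lower (6 and 3 over the list alone), led by the metallothioneins Mt1 and Mt2 (4.74-fold and 5.22-fold), which were also the 2 higher of 30 atrophy genes (1 lower, the proteasome gene Psmd8). The antioxidant list passed with fry (adjusted p = 0.0089) but not with camera (adjusted p = 0.109, and 0.62 with an estimated correlation). Higher and lower were 0 and 3 of 28 for lipid synthesis (Srebf1 fell 1.94-fold, adjusted p = 0.000658), 3 and 1 of 34 for fatty acid oxidation, 2 and 0 of 22 for the tricarboxylic acid cycle, 1 and 0 of 19 for mitochondrial biogenesis and 2 and 0 of 17 for slow fibres. They were 3 and 3 of 30 for insulin signalling, 0 and 1 of 19 for heat shock, 3 and 0 of 25 for the integrated stress response and 0 and 1 of 15 for mitochondrially encoded genes. Among markers of other cells they were 0 and 0 of 12 for tenocytes, 0 and 1 of 14 for adipocytes (Lep), 0 and 1 of 16 for endothelium, 1 and 3 of 14 for smooth muscle, 0 and 1 of 7 for erythroid cells and 1 and 0 of 14 for Schwann cells. Lymphocyte, neutrophil and sex-linked lists had 2, 2 and 4 tested genes, too few for a list test, and none changed.

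The next contrast asked what changed in muscle that lacked both kinases. Of the fixed lists, 15 of 20 macrophage, 10 of 16 fibro-adipogenic progenitor, 11 of 29 matrix, 10 of 40 oxidative phosphorylation and 10 of 40 ribosomal protein genes rose. Among 21 fast fibre genes 6 fell, among 29 glycolysis genes 5 fell and 1 rose, among 28 calcium handling genes 9 fell and 4 rose, and among 15 mitochondrially encoded genes 4 fell. All of these lists passed as sets with a preset correlation and none with an estimated one (camera adjusted p = 0.672 with an estimated correlation), and with quantile normalisation the median was 0 for fast fibre genes and 0.04 for mitochondrially encoded genes. The rotation test fry passed calcium handling (adjusted p = 0.00562) and none of the others, with 0.0837 for the macrophage list. In all, 3368 genes changed (25.6%), 1476 higher and 1892 lower, with 242 and 173 of them at least 2-fold, and the groups did not overlap for 55% of tested genes, where chance gives 10%. Ostn fell 10.75-fold from 28.6 ± 7.67 to 1.72 ± 0.567 (SD, n = 3; limma adjusted p = 4.16e-05), and Pla2g7 fell 7.44-fold (adjusted p = 1.17e-05). The other large falls were in the glycosyltransferase gene Galnt2 (8.91-fold, adjusted p = 0.0202), Pdpr, a regulator of pyruvate dehydrogenase (6.03-fold), Cdh4, a cadherin (5.94-fold), and Rasd2 (5.74-fold). Sln rose 15.1-fold from 1.49 ± 0.229 to 39.6 ± 18.7 (adjusted p = 0.00519), Myh3 7.69-fold (adjusted p = 0.0178), Fam171b 7.27-fold (adjusted p = 0.00386) and Ucp2, a mitochondrial carrier, 7.09-fold from 22.5 ± 3.75 to 170.4 ± 56.0 (adjusted p = 0.000219). Hmga1b was at least 153-fold higher against its floor, with the limit on its close copy given above. Adnp measured 0.0607 ± 0.0398 in the controls and 32.1 ± 2.61 in the p38α/γ KO (adjusted p = 0.0103). It shares its span with the gene model Gm20716, which had no inferred read in the p38α/γ KO libraries and measured 39.1 to 42.9 in the controls. In the p38α KO libraries Adnp measured 26.2, 0.0202 and 22.6 and Gm20716 0.0183, 35.4 and 8.80, and the sum of both was 41.2 ± 1.86 in the controls and 32.2 ± 2.61 in the p38α/γ KO.

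Leaving out 1 library gave counts of 1107 (control 1), 1646 (control 2), 1186 (control 3), 5388 (p38α KO 1), 859 (p38α/γ KO 2) and 1020 (p38α/γ KO 3). With the 6 libraries alone the count was 5536, and 5637 with the replicate number as a block in those 6. With that block in all 9 libraries it was 2320, with 2242 of the 3368 genes still called, so the list counts below hold for the fit without a block. The call of Galnt2 was lost without any 1 of the controls or p38α/γ KO 2 or 3 (up to adjusted p = 0.0844; all alternatives from 0.000372 to 0.0844; log2 −4.00 without p38α/γ KO 1 and −3.16 with all libraries), and that of Myh3 without control 1, control 3, p38α/γ KO 2 or p38α/γ KO 3 (up to 0.0766; all alternatives from 0.000154 to 0.0766). With a pseudocount of 5, and with none, log2 was −2.30 and −4.07 for Ostn, 2.69 and 4.62 for Sln, 2.20 and 3.26 for Myh3, 2.04 and 3.24 for Fam171b, −2.55 and −3.40 for Galnt2, −1.61 and −3.16 for Cdh4 and 0.76 and 3.12 for Cxcl10.

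Of 20 macrophage genes 15 rose and none fell, also 15 when adjusted over the list alone, with a median of 1.13 (camera adjusted p = 3.78e-06, and adjusted p = 0.672 with an estimated correlation). Cd74 rose 3.04-fold to 163.2 ± 27.0 (SD, n = 3; limma adjusted p = 0.00409) and C1qc 3.16-fold (adjusted p = 0.0111). Of 29 matrix genes 11 rose, 13 when adjusted over the list alone (median 0.82, camera adjusted p = 7.12e-05), and of 16 progenitor genes 10 rose, 11 over the list alone (median 0.55, camera adjusted p = 0.000544), both with adjusted p = 0.672 with an estimated correlation. Postn rose 5.74-fold (adjusted p = 0.015), a call lost without control 1, control 3 or p38α/γ KO 2 (up to 0.0664; all alternatives from 1.83e-05 to 0.0664). Mmp14, a membrane-bound matrix protease, rose 2.21-fold (adjusted p = 0.0122), a call lost without control 3 or p38α/γ KO 2 (up to 0.0577; all alternatives from 0.000106 to 0.0577). Of 17 NF-kB genes 7 rose and of 25 interferon genes 7 rose, with the same counts over each list alone (camera adjusted p = 0.00631 and 0.00492, both with adjusted p = 0.672 with an estimated correlation). Cxcl10, a chemokine gene in the NF-kB list, rose 3.51-fold (adjusted p = 0.00616). Of 25 immediate early genes 9 rose, also 9 over the list alone (median 0.42, camera adjusted p = 0.000938, and adjusted p = 0.672 with an estimated correlation), with Jund 1.98-fold and Maff 1.71-fold higher. Of 22 myogenesis genes 5 rose and 1 fell, 10 and 1 when adjusted over the list alone (camera adjusted p = 0.000988, and adjusted p = 0.672 with an estimated correlation). The NF-kB call was lost without p38α/γ KO 1 (0.0522).

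Of 40 oxidative phosphorylation genes 10 rose, 12 when adjusted over the list alone, and of 40 ribosomal protein genes 10 rose, 11 over the list alone. Their medians were 0.25 and 0.22 (camera adjusted p = 0.000195 for both, and adjusted p = 0.672 with an estimated correlation). Of 15 mitochondrially encoded genes 4 fell, also 4 over the list alone (camera adjusted p = 0.0419, and adjusted p = 0.672 with an estimated correlation). They included mt-Nd5 (2.42-fold), mt-Nd4l (2.60-fold) and mt-Atp8 (2.64-fold, limma adjusted p = 0.00841). The mitochondrial list's median was −0.27, but 0.04 with quantile normalisation, where the call was lost (0.831), and it was lost without control 1, control 3, p38α KO 1, p38α KO 3 or p38α/γ KO 2 (up to 0.121). Fast fibre genes had 6 of 21 lower (6 over the list alone), with Myl1 1.62-fold lower at 5339 ± 44.2 (SD, n = 3; limma adjusted p = 0.00932, and 0.053 with quantile normalisation, where its call was lost). Glycolysis and glycogen genes had 5 of 29 lower and 1 higher (5 and 0 over the list alone), with Phka1 2.10-fold lower (adjusted p = 0.00354). Calcium handling genes had 9 of 28 lower and 4 higher (11 and 4 over the list alone), with Stac3 1.33-fold lower and the calcium-binding Casq2 4.39-fold higher (adjusted p = 0.00948). Clock genes had 4 of 19 lower (6 over the list alone), with Cry1 1.74-fold lower (adjusted p = 0.00522) and Nr1d2 1.46-fold lower. The camera adjusted p of these 4 lists was 0.0102, 0.0445, 0.0445 and 0.0419, each with adjusted p = 0.672 with an estimated correlation.

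With quantile normalisation the fast fibre (adjusted p = 0.889, median 0), glycolysis (0.447), calcium (0.397) and clock (0.0984) calls in the double knockout were lost. Without p38α/γ KO 1 they were lost too (0.0648, 0.165, 0.083 and 0.0648), as were glycolysis, calcium and clock without control 3 (0.0555, 0.0669 and 0.0674), glycolysis without control 1 (0.0803), and glycolysis and calcium without p38α KO 2 (0.0501 for both). Over the 14 lists that passed, the alternatives gave adjusted p from 1.69e-09 to 0.889.

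The other 20 tested lists did not pass in the p38α/γ KO. Higher and lower genes were 5 and 7 of 26 for the p38 pathway (5 and 9 when adjusted over the list alone), 2 and 4 of 12 for JNK, ERK and other kinases, with Mapk6 1.63-fold lower, and 7 and 1 of 24 for myokines. Insulin signalling had 3 and 8 of 30, with Rps6kb1, the S6 kinase, 1.44-fold lower (limma adjusted p = 0.00948) and Trib1 1.75-fold higher. Antioxidant genes had 6 and 3 of 23 (9 and 3 over the list alone), with Mt1 4.44-fold higher, and this list passed with the replicate number as a block (camera adjusted p = 0.0445, against 0.0576 without it), but not with an estimated correlation (adjusted p = 0.672 with an estimated correlation, without the block). It also passed in the rotation test fry (adjusted p = 0.00398, without the block). Higher and lower were 1 and 3 of 28 for lipid synthesis, with Srebf1 1.71-fold lower (adjusted p = 0.00181), and 4 and 0 of 34 for fatty acid oxidation, with the lipid droplet gene Plin2 1.58-fold higher and Hadh 1.77-fold higher. Higher and lower were 2 and 0 of 17 for slow fibres (median 0.48), 1 and 2 of 22 for the tricarboxylic acid cycle, 2 and 3 of 19 for mitochondrial biogenesis and 3 and 2 of 30 for atrophy genes. They were 4 and 0 of 23 for denervation, with Gadd45a 3.16-fold higher, 1 and 3 of 19 for heat shock, with the chaperone Hspa8 1.56-fold lower, and 2 and 0 of 25 for the integrated stress response, with Slc7a5 1.89-fold higher. Among markers of other cells they were 1 and 0 of 12 for tenocytes, 1 and 1 of 14 for adipocytes, 1 and 3 of 16 for endothelium, 1 and 4 of 14 for smooth muscle, 0 and 2 of 7 for erythroid cells and 0 and 0 of 14 for Schwann cells. Lymphocyte and neutrophil lists had 2 tested genes each and none changed. The 4 tested sex-linked genes all lie on chromosome Y and fell, among them Uty (1.79-fold, adjusted p = 0.00599) and Eif2s3y (1.58-fold, adjusted p = 0.0083).

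**Figure D2:**
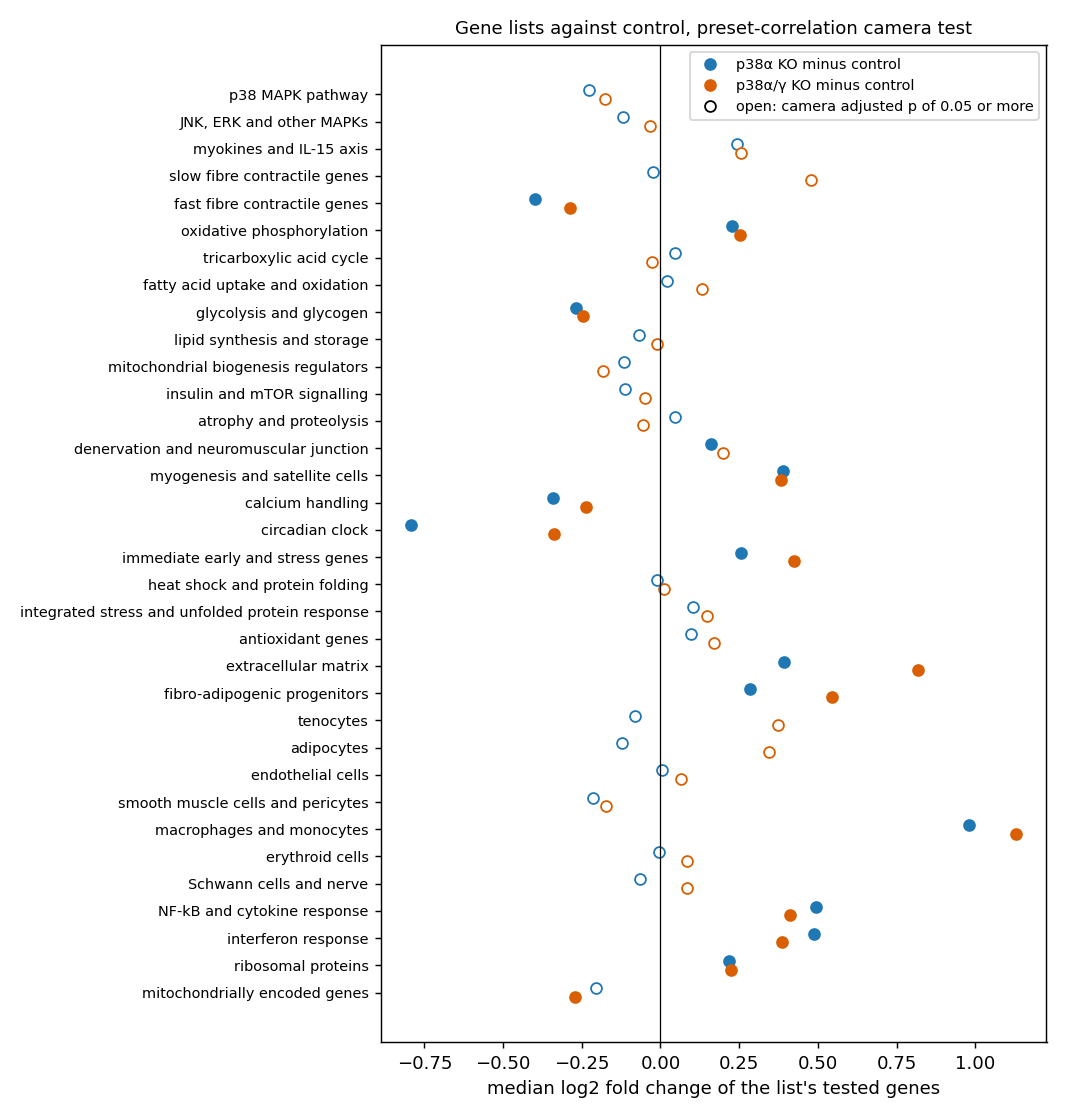
Median log2 fold change of the tested genes of each gene list in the p38α KO (blue) and the p38α/γ KO (orange) against control, filled where camera with a preset correlation gave an adjusted p below 0.05. Macrophage genes lie farthest to the right (0.98 and 1.13) and clock genes of the p38α KO farthest to the left (−0.79); no list passed with an estimated correlation, and the mitochondrially encoded and fast fibre medians of the p38α/γ KO were 0.04 and 0 with quantile normalisation.

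The direct contrast of the p38α KO with the p38α/γ KO asked what the added loss of p38γ changed. Of the targeted genes Mapk12 differed, at 101.5 ± 4.46 in the p38α KO and 33.2 ± 2.18 in the p38α/γ KO (SD, n = 3; log2 1.59, limma adjusted p = 8.91e-06). Mapk14 did not differ (log2 −0.04, adjusted p = 0.932; −0.16 to 0.11 on leaving out 1 library). In all, 58 genes changed, 16 higher and 42 lower in the p38α KO, and 1573 had an unadjusted p below 0.05. Of the 58, 40 were protein-coding and 13 pseudogenes. Ucp2 was 3.07-fold lower in the p38α KO (53.2 ± 8.37 against 170.4 ± 56.0, SD, n = 3; adjusted p = 0.0133), Mylk4 2.59-fold lower (375 ± 76.8 against 959 ± 48.9, adjusted p = 0.00611), Dbp 2.60-fold lower (adjusted p = 0.0326), Map3k7cl 2.60-fold lower (adjusted p = 0.0326) and Amd1, an enzyme of polyamine synthesis, 2.42-fold lower (adjusted p = 0.0128). Higher in the p38α KO were Mybph, a myosin-binding protein (490.7 ± 167 against 70.4 ± 57.7, 8.05-fold, adjusted p = 0.0222), Ttc38 (2.53-fold, adjusted p = 0.00198), the mast cell protease Tpsab1 (2.47-fold, adjusted p = 0.0133) and Mtap (2.01-fold, adjusted p = 0.0348). Tagap was 2.56-fold higher (adjusted p = 0.0384) and its neighbour Tagap1 3.34-fold lower (adjusted p = 0.00207). Tagap1 and Tagap, near 7 and 8 Mb, and Tpsab1 lie on the chromosome of Mapk14, Ttc38 lies on that of Mapk12 and Mylk4 lies on chromosome 13. The share of called genes within 20 Mb of Mapk14 or Mapk12 was 1.56%, against 0.364% elsewhere. It was 1.88% around Mapk14 alone and 1.16% around Mapk12 alone.

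The direct count was 1872 without p38α KO 1, 23 without p38α KO 2, 38 without control 3, 37 without p38α/γ KO 1 and 24 without p38α/γ KO 3, and it was 22 with the 6 libraries alone. It was 6087 with array weights, which did not converge, and 3197 with the weights updated gene by gene, so the number of genes that differ between the knockouts was not fixed by these data. Of the genes named, Mapk12, Ttc38, Tagap1 and Mylk4 passed with each library left out. Leaving out 1 library ended the calls of Ucp2 (p38α KO 2 or p38α/γ KO 3, up to 0.0869), Amd1 (p38α/γ KO 1 or 3, up to 0.0728), Tpsab1 (p38α KO 2 or any p38α/γ KO library, up to 0.0807), Mybph (control 2 or 3, p38α KO 2 or 3, p38α/γ KO 1 or 3, up to 0.124; log2 3.63 without p38α/γ KO 2 and 3.01 with all libraries), Dbp (control 2 or 3, p38α KO 2 or 3 or any p38α/γ KO library, up to 0.0951) and Tagap (the same libraries as Dbp, up to 0.173). Those of Map3k7cl (any control, p38α KO 2 or any p38α/γ KO library, up to 0.168) and Mtap (any library but p38α KO 1, up to 0.178) ended as well. Over all alternatives the highest adjusted p were 0.185 for Ucp2, 0.271 for Amd1, 0.213 for Tpsab1, 0.124 for Mybph, 0.0951 for Dbp, 0.185 for Tagap, 0.283 for Map3k7cl, 0.22 for Mtap, 0.119 for Mylk4, 0.119 for Tagap1 and 0.0458 for Ttc38. With the 6 libraries alone the calls of Ucp2, Amd1, Tpsab1, Mybph, Dbp, Tagap, Map3k7cl and Mtap were lost. With a pseudocount of 5, and with none, log2 was 0.50 and 2.67 for Tagap, whose call was lost without a pseudocount (adjusted p = 0.079), 0.42 and 3.41 for Tpsab1 and −1.14 and −2.02 for Tagap1.

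Between the knockouts 8 lists passed, 1 higher and 7 lower in the p38α KO. Interferon genes lay higher (median 0.15, camera adjusted p = 0.024), with 0 of 25 past the gene test and 1 over the list alone. Slow fibre (−0.60, 0.0158), fast fibre (−0.13, 0.0235), clock (−0.25, 0.0104), matrix (−0.32, 0.0158), progenitor (−0.25, 0.0158), tenocyte (−0.31, 0.033) and adipocyte (−0.56, 0.0263) genes lay lower, each with median and camera adjusted p. All 8 had adjusted p = 0.961 with an estimated correlation, the highest of alternatives that began at 6.75e-09. Single genes passed in the clock list, Bhlhe41 (1.76-fold lower, limma adjusted p = 0.0183) and Dbp, and in the fast fibre list, Mylk4. Without p38α KO 1 the fast fibre (0.671), clock (0.245), adipocyte (0.119) and interferon (0.405) calls were lost, and without p38α KO 3 the slow fibre (median 0.04, 0.955), progenitor (0.374) and tenocyte (0.112) calls, while the matrix median turned to 0.07 (0.823). Without p38α KO 2 the tenocyte (0.591) and adipocyte (0.16) calls were lost. Without p38α/γ KO 2 those of fast fibre (0.111), matrix (0.185), progenitor (0.119), tenocyte (0.212), adipocyte (0.119) and interferon (0.206) genes were lost, without p38α/γ KO 1 those of tenocyte (0.09) and interferon (0.375) genes and without p38α/γ KO 3 those of slow fibre (0.051) and adipocyte (0.0702) genes. The Bhlhe41 call was lost without p38α KO 2, p38α/γ KO 2 or p38α/γ KO 3 (up to 0.0835; all alternatives from 0.000107 to 0.213) and with the 6 libraries alone (0.0502). The remaining 26 tested lists did not pass.

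**Figure D3:**
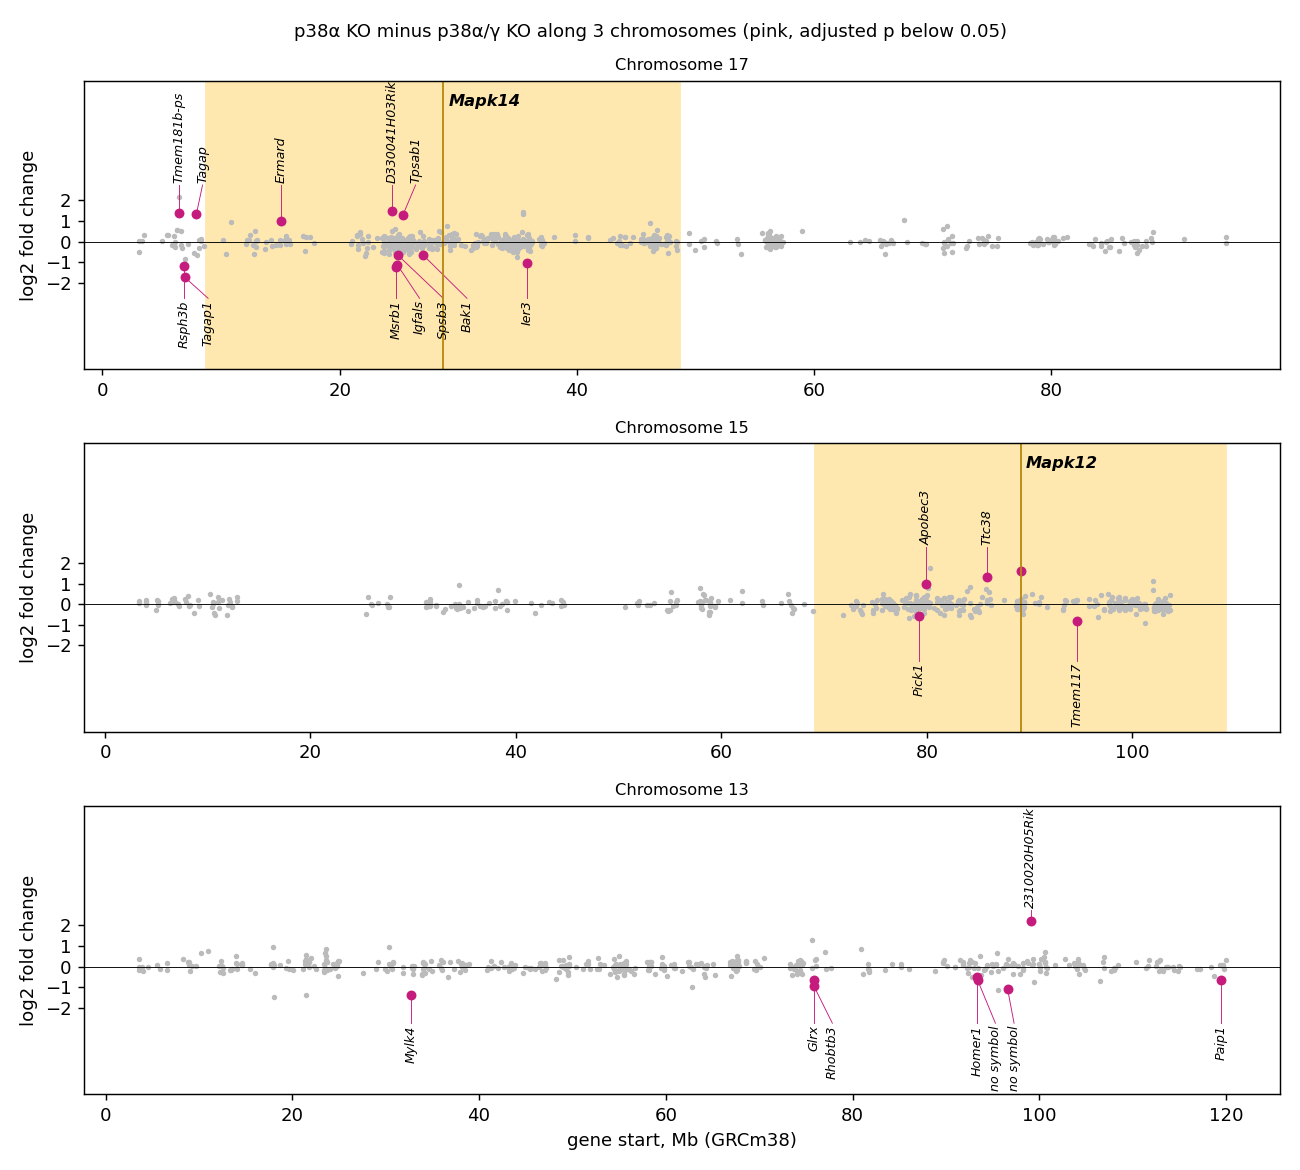
Log2 fold change of the p38α KO minus the p38α/γ KO against gene start (Mb, GRCm38) on chromosomes 17, 15 and 13, with genes of adjusted p below 0.05 in pink and the 20 Mb to either side of Mapk14 and Mapk12 shaded. The shaded windows hold 12 called genes besides the targets, and chromosome 13 holds 8.

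The changes of the knockouts against control ran largely in parallel. Both shared the same 3 control libraries, which raises any likeness between them. Genes past the threshold with the same direction in both numbered 1662, with 626 higher and 1036 lower, and 4 genes went opposite ways. Independent lists of these sizes would share 108.1 higher and 197.3 lower genes, and 100 simulations of unchanged groups against the same controls shared 0.01 on average. Such groups give almost no calls, so that value does not measure how many calls shared controls add where real changes exist. The log2 fold changes of the knockouts had a Pearson correlation of 0.806 across genes, which are not independent replicates, against a simulated mean of 0.496. Their covariance was 0.165, against 0.0197 in the simulations, a difference of 0.145. The correlation was 0.648 without p38α KO 1. The 3 controls were too few to split, so part of the excess may come from the shared controls. By threshold, 666 genes changed in the p38α KO alone and 1702 in the p38α/γ KO alone, and of these 2368, 46 differed in the direct test. That number rests on the 58 direct calls, which were 1872 without p38α KO 1, 23 without p38α KO 2 and 3197 with array weights updated gene by gene, so it does not show that the others changed alike. The shared count was 517 without control 1, 680 without control 2, 514 without control 3, 1105 without p38α KO 2, 638 without p38α/γ KO 2 and 711 without p38α/γ KO 3, and 1041 with the replicate number as a block. Pla2g7, Ostn, Mt1, Map2k6 and Cd74 were among the genes that changed the same way in both knockouts.

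**Figure D4:**
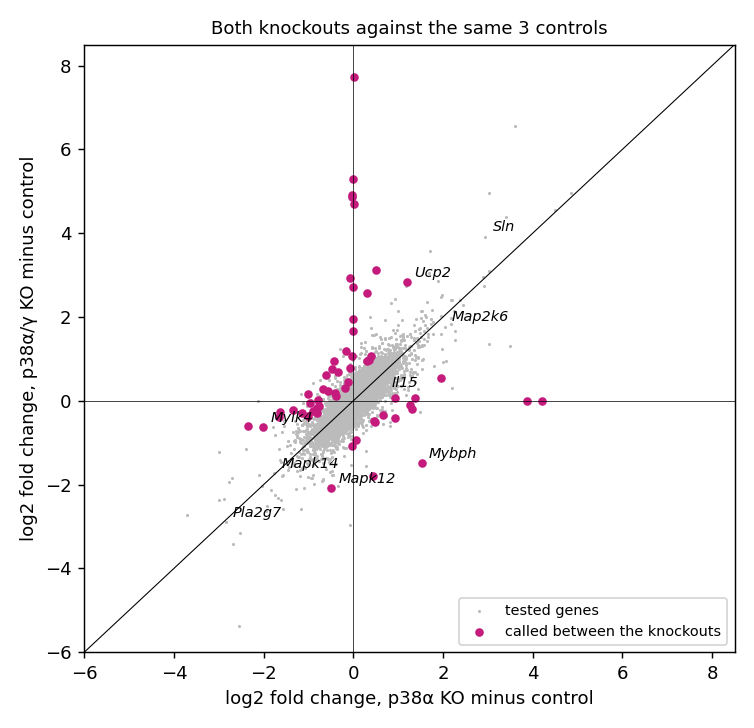
Log2 fold change against control of each tested gene (grey points) in the p38α KO and the p38α/γ KO, with the line of equal change and, in pink, the 58 genes called between the knockouts. Most genes lie along the line (Pearson correlation 0.806, where shared controls alone gave 0.496), and Mapk12, Ucp2, Mylk4 and Mybph lie off it.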

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

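The tests that weigh the 3 patterns below were chosen after the results were seen, whereas the comparison of the knockouts and the fits with 1 library left out were fixed before the data were examined and the tests on other splits were written before their result was seen. Of the genes named in the comparisons with control, 5 changed differently in the knockouts by the direct test, given here as the difference in log2 change against control (p38α KO minus p38α/γ KO) and its limma adjusted p. They were Mapk12 (1.59, 8.91e-06), Mylk4 (−1.37, 0.00611), Ucp2 (−1.62, 0.0133), Ier3 (−1.03, 0.0193) and Dbp (−1.38, 0.0326). For Mapk12 the design gives the biological explanation, since only the p38α/γ KO was made to lack it. Ier3, a stress-induced gene, measured 8.79 ± 0.597 in the controls, 6.77 ± 1.43 in the p38α KO and 14.8 ± 2.30 in the p38α/γ KO (SD, n = 3), and it lies near Mapk14. Its call was lost without p38α KO 2 or any p38α/γ KO library (adjusted p up to 0.0999).

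The first pattern was a set of 17 called genes with no inferred read in any library of 1 group, among them Hmga1b. Pseudogenes made up 64.7% of the 17, against 2.07% of the other tested genes, a ratio of 31.2 (Fisher p = 4.24e-15), which fits reads that moved between near-identical or overlapping gene copies. The 17 were selected for having no inferred read in 1 group, and the other genes were not matched to them on level. The ratio therefore cannot tell moved reads from a low level of these genes. Of the 17 genes 5.88% lay within 20 Mb of Mapk14 or Mapk12, so most did not themselves lie near those loci. The positions of the copies that may share their reads were not examined. DNA of another strain linked to the loci was therefore not excluded, and such DNA elsewhere was not tested. For Adnp, the sum with Gm20716 differed 1.28-fold between the controls and the p38α/γ KO, which fits reads moved between these overlapping models. Hmga1b and Adnp may therefore hold reads of their copies, and their changes cannot be taken as changes in transcription. Dynlt1b was not among the 17 genes and was not summed with its near-identical copies. It may hold their reads as well, but this was not tested.

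The second pattern was the position of genes called between the knockouts. Leaving out the targets, 12 of 771 genes within 20 Mb of Mapk14 or Mapk12 were called, against 45 elsewhere, a ratio of 4.27 (Fisher p = 9.45e-05, adjusted over 15 window tests 0.00142). Around Mapk14 alone 8 of 425 genes were called (ratio 4.88, Fisher adjusted p = 0.00348). Around Mapk12 alone, the locus that differs by design, it was 4 of 346 (ratio 2.79, Fisher adjusted p = 0.158). The pooled value fits DNA of another strain flanking the targeted loci, but neighbouring genes can also be affected by the deletions themselves, which was not tested. Mapk14 was targeted in both knockouts, so its deletion is shared and would not by itself set them apart. The same windows were not enriched for genes changed against control (Fisher adjusted p = 0.156 to 1). Outside them 17.6% of genes were called in the p38α KO and 25.6% in the p38α/γ KO, so a few linked genes could not show. Chromosome 13, which holds neither target, had 8 of 471 genes called between the knockouts (ratio 4.39, Fisher adjusted p = 0.00456). It was chosen after the results were seen and no other whole chromosome was tested, so its adjusted p does not cover that choice. The differences of Tpsab1, Ttc38 and Ier3 may thus reflect the origin of the DNA, and Tagap and Tagap1 lie on chromosome 17 outside the window. Mylk4 starts at 32700834 on chromosome 13, and the other called genes of that chromosome start at 75839868 or beyond. Whether its difference reflects the origin of the DNA was not tested.

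The third pattern was the rise of macrophage markers in both knockouts. A lower share of muscle fibre RNA that raised all other cell types alike did not account for it, since the mean of the medians of endothelial, Schwann, tenocyte and smooth muscle lists was at most 0.0774 of the macrophage median; but the medians in the p38α/γ KO were 0.373 for tenocyte, 0.545 for progenitor and 0.818 for matrix genes, so a higher share of some other cells besides macrophages stayed open. Library 1 of the p38α KO alone did not account for it either, since the median without it was 0.799. A hypothesis is a regeneration-like state that varies between animals. Across the 6 knockout libraries the macrophage score and the level of Myh3 and Myh8 had a Pearson correlation of 0.809 (exact permutation p = 0.0653, 720 permutations). Spearman rho was 0.886 (exact permutation p = 0.0333), and 1 relation was computed. Pearson r was 0.975 without the 2 libraries farthest from the median score, p38α KO 3 and p38α/γ KO 3. Those 2 had the lowest scores (2.76 and 2.86). The test left the hypothesis open.

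Other splits of the same 6 libraries were tested for each count of changed genes. Of 10 splits, as many changed genes came from 1 in the p38α KO against control, 1 in the p38α/γ KO against control and 2 between the knockouts, the real split included. The highest other counts were 0, 1 and 811. With 10 splits the share cannot fall under 0.1, so an origin of these counts in chance assignment of libraries stayed open for all 3. The split with 811 set p38α KO 1 with p38α/γ KO 2 and 3, so the direct comparison holds structure among the samples that does not follow genotype.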

How the results depend on the processing

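The alternatives with array weights updated gene by gene, vooma weights, no pseudocount and the block in 6 libraries were chosen after the results were seen, and the cause of each difference below was not tested. Genes changed in the p38α KO against control (2332) numbered 7475 with array weights, which did not converge, 5108 with array weights updated gene by gene, 1364 with only the 2 groups compared, 212 with the replicate block in those 6 libraries, 3572 at adjusted p below 0.1, 1144 with an absolute log2 change of at least 0.58, and 837 to 3257 with 1 library left out. In the p38α/γ KO (3368) they numbered 6740, 6452, 5536, 5637 with the block in 6 libraries, 1631 with the fold threshold, and 859 to 5388 with 1 library left out. Between the knockouts (58) they numbered 6087, 3197, 22, 32 with the replicate block, 16 with the block in 6 libraries, 121 at adjusted p below 0.1, and 23 to 1872 with 1 library left out. Genes changed in the same direction in both knockouts (1662) numbered 4461 and 3507 with the array weights, 1041 with the replicate block, 192 with the block in 6 libraries, 2699 at adjusted p below 0.1, 754 with the fold threshold, and 514 to 2417 with 1 library left out. The fold change correlation (0.806) was 0.663 and 0.687 with the array weights and 0.648 to 0.827 with 1 library left out.

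Il15 in the p38α KO kept its log2 change of 0.69 with only the 2 groups (adjusted p = 0.0728), with the replicate block (0.0588) and with the block in 6 libraries (0.0792) but was no longer called, and it was 0.60 to 0.87 with 1 library left out. Il15 between the knockouts was called with array weights (0.56, adjusted p = 0.00414) and with the gene-by-gene update (0.52, 0.0431). Mapk12 in the p38α KO (−0.49) was not called with the block in 6 libraries (0.0655). Mapk14 between the knockouts, not called, turned to 0.0699 and 0.0510 with the array weights and lay between −0.16 and 0.11 with 1 library left out. Mapk11 in the p38α KO, not called, lay between −0.241 and 0.0717 with 1 library left out, and the median of the matrix list between the knockouts between −0.72 and 0.0677, above 0 only without p38α KO 3. The lists that passed (14, 14 and 8) numbered 0, 0 and 0 with an estimated correlation and 7, 2 and 0 with fry, and 9 to 17 in the p38α/γ KO and 4 to 9 between the knockouts with 1 library left out. The 7 and 2 include the antioxidant list (fry adjusted p = 0.0089 and 0.00398), which camera did not pass. Fry did not pass the macrophage list (0.0533 in the p38α KO and 0.0837 in the p38α/γ KO). Nor did it pass the matrix (0.452 and 0.15), progenitor (0.284 and 0.0837), oxidative phosphorylation (0.245 and 0.15) or ribosomal protein (0.149 and 0.125) lists.

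Of the 182 other named calls none turned direction. They stayed called in 170 cases with quantile normalisation, 155 with the replicate block, 160 with only the 2 groups, 126 with the block in 6 libraries, 176 without the trend, 179 with vooma weights and 178 with a pseudocount of 5, and in 1263 cases (375 lost) with 1 library left out. Of the 2332, 3368 and 58 calls, 829 to 2100, 853 to 3368 and 22 to 58 stayed called with 1 library left out, 1502, 2242 and 31 with the replicate block, and 211, 3358 and 14 with the block in 6 libraries. A balanced block leaves the differences themselves unchanged. Folds of genes near 0 in 1 group depend on the pseudocount, as given in the report. TMM factors, median of ratios, the robust fit and no low-value filter changed no count by over 1.5 times. The deposited values were already normalised, and TMM factors and median of ratios moved the median log2 change by only −0.00556 to 0.00131. Such small shifts say little about how the counts depend on scaling. For the p38α/γ KO, same-numbered libraries correlated weakly with the controls (0.11, 0.12 and 0.15), which does not establish that they are paired. There the block in all 9 libraries gave 2320 genes, so the counts of called list members also depend on it. Of the genes and lists named in the report for that comparison, only the antioxidant list changed its call, as given there. In the other comparisons the libraries share only a number. Tests on counts, planned for files of counts, were not run. Depth limits genes near a value of 0.1, which is about 3 reads.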

Other observations

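The genes of this part were chosen after their values were seen, and none was in the rule for named genes. Among genes called between the knockouts, Tcap, which encodes the sarcomere protein telethonin, measured 2673 ± 197 in the controls, 1794 ± 135 in the p38α KO and 3159 ± 475 in the p38α/γ KO (SD, n = 3; log2 −0.81, limma adjusted p = 0.0384). Fhl3, a LIM domain protein of muscle, measured 360.8 ± 32.7, 163.1 ± 16.3 and 296.4 ± 40.3 (log2 −0.85, limma adjusted p = 0.0157). The Fhl3 call was lost without p38α KO 2, p38α/γ KO 2 or p38α/γ KO 3 (adjusted p up to 0.0917), and the Tcap call without any 1 of the controls or those 3 libraries (up to 0.201).

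Several processed pseudogenes had nearly all their inferred reads in 1 group. Those below belong to the first pattern above, where reads may have moved between near-identical copies. Their values therefore cannot be taken as changes in transcription. Rpl3-ps1 had no inferred read in the controls or the p38α KO and measured 39.0 ± 2.83 in the p38α/γ KO, and Gm15459 measured 232.8 ± 117 there and at most 0.0306 ± 0.0197 on average elsewhere (SD, n = 3). Gm15487 and Gm9825 had no inferred read in the controls or the p38α/γ KO and measured at least 125-fold and 87.4-fold above their floor of 3 reads in the p38α KO, against the controls.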
